A study of Homo sapiens with 6 samples.

How the data were processed

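Polyadenylated RNA was sequenced from EA.hy926 cells, 3 libraries of cells at 20% oxygen (normoxia) and 3 of cells kept at 1% oxygen for 8 h (hypoxia). Per the labels' protocols, RNA was taken up in Trizol and libraries were made with a NEBNext Ultra RNA kit for Illumina sequencing. The submitters' processing notes list CASAVA, HISAT2 version 2.0.5 and featureCounts version 1.5.0-p3, with no order or settings. They also list the mouse build mm9, which cannot be the build behind this table, because all 22153 gene identifiers in it are human Ensembl identifiers. The genome build, the annotation release and the strand setting used for counting are not given in the sources used here.

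The deposited table is named for FPKM, but its signal is of another kind. Within each library, 100% of the deposited values were whole multiples of a single step, with a tolerance of 0.05 of a step, and the step did not depend on the gene. The deposited signal is therefore whole read counts per gene divided by a single size factor per library, with no division by gene length and no scaling to a common depth. The size factors ran from 0.944 to 1.06 and matched median-of-ratios size factors recomputed from the recovered reads. Read counts were recovered by dividing by the step. The libraries held from 17226736 reads (normoxia replicate 1) to 18652704 reads (hypoxia replicate 2) assigned to genes, with reads in 16741 to 18858 genes per library. No gene in the table had fewer than 2 reads over the 6 libraries. The order of genes in the table followed the p-values of a DESeq2 test between the groups recomputed here (Spearman rho across genes 0.999997).

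All identifiers were found in GENCODE release 29 (GRCh38), which gave gene length, GC content, biotype and position, and 21988 had a symbol in the name table. Positions in the text are from that release, matched by identifier, and are not the authors' coordinates. Exon overlaps between genes were taken from the same release.

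The test had been planned for FPKM. Once the true unit was known, and before any test was run, the deposited values were put on an FPKM scale so that the planned filter and pseudocount could be kept. Each value was divided by the summed exon length and by the mean library total, in the units of FPKM, which keeps the deposited size factors. Genes with an FPKM of 1 or more in at least 3 libraries were tested, 10237 in all. log2(FPKM + 0.1) was fitted with limma 3.58.1 (R 4.3.3) with group as the only term, a mean-variance trend and robust variance estimates. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and an adjusted p below 0.05 as the threshold. Fold changes on this scale understate the change of weakly expressed genes. Means and SDs in the text are of the deposited size-factor-scaled read counts, n = 3 per group, and a fold is the ratio of the group means of those values. Log2 fold changes, standard errors and adjusted p-values are from the limma fit unless another tool is named. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

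The 25 gene lists, the test, a first set of alternative settings and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members, 23 of them, were tested with camera at a preset inter-gene correlation of 0.01, against all other genes tested, with adjustment over the lists. Camera with an estimated correlation, and fry, which tests a list against no change, were run beside it. Named genes were up to 12 protein-coding genes in each direction with the largest changes past the test, with groups that did not overlap and a mean FPKM of at least 5 in the higher group. From each list, 2 to 4 members past the test with the largest changes were named, or the 2 with the largest changes where fewer than 2 passed. In the epithelial and coagulation lists, 1 gene each that this rule names is left out of the text. HIF1A, EPAS1, ARNT, VEGFA, CA9, EGLN1, EGLN3, ACTB and GAPDH were always to be named, and up to 4 lncRNA genes in each direction with a mean FPKM of at least 1. EGLN3 was not analysed here. Shares of lncRNA genes were compared with Fisher's exact test.

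The fit was tested on simulated reads for the same 10237 genes, with 200 genes changed in each of 10 simulations at each gene's spread in the real libraries. Reads were drawn independently for each gene, so variation shared between genes, such as GC trends of libraries, was not simulated. The fit recovered 7.65% of genes changed 2-fold, 77.9% of those changed 4-fold and 95.7% of those changed 8-fold. Unchanged genes made up 5.23% of the calls, and 0 changed genes were called in the wrong direction. In these simulations changes near 2-fold were therefore mostly out of reach of this design, and the rates may differ for the real libraries.

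The alternatives chosen in advance were other pseudocounts, no filter or a stricter filter, 4 other scalings, a fit with no variance trend, a replicate block and the omission of each library. Alternatives chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, limma on the deposited values with no length scaling, per-library loess corrections for GC content and gene length (span 0.3), a covariate for the direction of each library's GC trend, and library quality weights. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.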

Results

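The data describe how the transcriptome of EA.hy926 cells differs after 8 h of low oxygen. EA.hy926 is a human line made by fusing umbilical vein endothelial cells with the lung carcinoma line A549, and it keeps many endothelial traits. Polyadenylated RNA was measured in 3 libraries of cells at 20% oxygen and 3 libraries of cells held at 1% oxygen for 8 h. Each library held between 17226736 and 18652704 reads assigned to genes. The table listed 22153 genes, of which 14565 are protein-coding and 4905 are lncRNA genes. The series' design names the question, which is the set of genes whose expression changes with 8 h of hypoxia.

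Hypoxia raised the transcripts of glucose uptake and glycolysis and of known targets of the hypoxia-inducible factors (HIF), the transcription factors stabilised at low oxygen. Of 10237 genes tested with limma, 10 passed the threshold, all of them higher in hypoxia and all by at least 2-fold. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose most, from 1242 ± 369 to 39891 ± 21025 size-factor-scaled reads (SD, n = 3 per group), 32.1-fold. MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210, rose 17.2-fold from 14.4 ± 12.1 to 249 ± 49.6. PFKFB4, a bifunctional kinase and phosphatase that sets the level of fructose 2,6-bisphosphate, rose 12.8-fold from 244 ± 92.0 to 3126 ± 1104. BNIP3, a mitochondrial outer membrane protein that acts in mitophagy, rose 11.2-fold from 596 ± 89.2 to 6695 ± 722.

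The other genes past the test were RASSF4, SLC2A1, SPAG4, ENO2, PGK1 and LDHA. The glucose transporter SLC2A1 went from 1186 ± 272 to 9564 ± 4271 scaled reads, 8.06-fold, and the enolase ENO2 from a mean of 350 to 2634 ± 1097, 7.53-fold. SPAG4, a protein of the nuclear envelope, went from 298 ± 78.3 to 2161 ± 360, 7.24-fold. The glycolytic enzymes PGK1 and LDHA were already abundant in normoxia, at 9768 ± 1263 and 13558 ± 1584, and reached 33133 ± 2440 and 43896 ± 3628, rises of 3.39-fold and 3.24-fold. RASSF4, a member of the Ras association domain family, went from 95.4 ± 6.63 to 1113 ± 254, 11.7-fold. The exons of RASSF4 share 695 bp with DEPP1 on the opposite strand, and DEPP1 stood at 364 ± 114 in normoxia and 4003 ± 2283 in hypoxia. The strand setting of the counting is not given in the sources used here, so reads of these neighbours cannot be fully told apart.

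**Figure D1:**
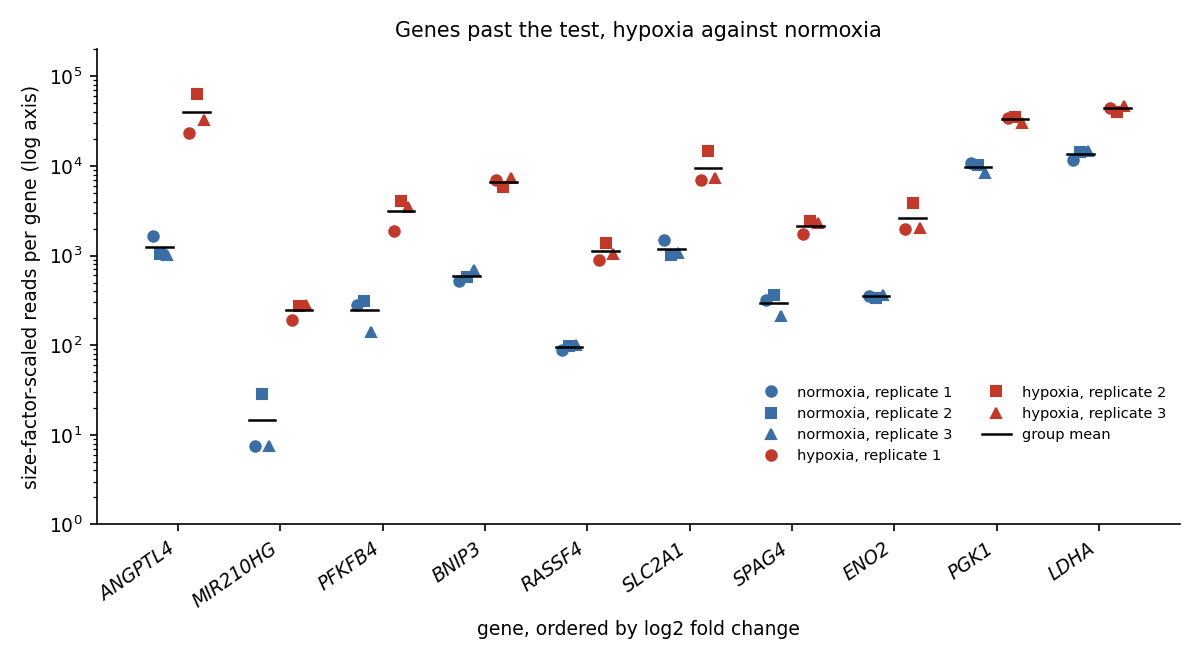
Size-factor-scaled reads per gene on a log axis for the 10 genes past the test, ordered by log2 fold change, with 1 point per library (normoxia blue, hypoxia red, marker shape by replicate) and a black line at each group mean. In each of the 10 genes the 3 hypoxia libraries lie above the 3 normoxia libraries, with group means 32.1-fold apart for ANGPTL4 and 3.24-fold apart for LDHA.

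On the log2 scale of the limma fit the changes were 4.91 (SE 0.38, adjusted p = 0.00758) for ANGPTL4, 3.47 (SE 0.21, adjusted p = 0.00207) for BNIP3 and 3.31 (SE 0.28, adjusted p = 0.00853) for RASSF4. SPAG4 changed by 2.86 (SE 0.27, adjusted p = 0.0146) and MIR210HG by 3.93 (SE 0.46, adjusted p = 0.0284). PFKFB4, SLC2A1, ENO2, PGK1 and LDHA shared an adjusted p of 0.0236, with log2 changes of 3.62, 2.94, 2.81, 1.77 and 1.70. At an unadjusted p under 0.05 there were 275 genes, below the 512 that chance gives for this number of genes tested. The groups did not overlap in 7.48% of the genes tested, beside 10% by chance. The count rests on every library: it was 4, 5 and 24 without normoxia replicates 1, 2 and 3, and 2, 3 and 1 without hypoxia replicates 1, 2 and 3, and BNIP3 alone was called in all 6 of these fits. It was 4 with no filter on low values, 22 and 28 after corrections for GC content without and with gene length, 64 with the direction of the GC trend as a covariate, 58 by DESeq2, 9 by edgeR and 4667 with library quality weights whose estimation did not converge, alternatives chosen after seeing the data apart from the filter.

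The 10 genes lie on 8 chromosomes in GENCODE 29 (GRCh38). ANGPTL4 (ENSG00000167772) is on the plus strand of chromosome 19 from 8363289 to 8374373. PFKFB4 (ENSG00000114268) is on the minus strand of chromosome 3 from 48517684 to 48562015. BNIP3 (ENSG00000176171) and RASSF4 (ENSG00000107551) are on chromosome 10, from 131966455 to 131982013 on the minus strand and from 44959407 to 44995891 on the plus strand. SLC2A1 (ENSG00000117394) is on the minus strand of chromosome 1 from 42925375 to 42959176. SPAG4 (ENSG00000061656) is on the plus strand of chromosome 20 from 35615892 to 35621049, and ENO2 (ENSG00000111674) on the plus strand of chromosome 12 from 6913745 to 6923698. PGK1 (ENSG00000102144) is on the plus strand of chromosome X from 77910739 to 78129296. LDHA (ENSG00000134333) and MIR210HG (ENSG00000247095) are on chromosome 11, from 18394388 to 18408425 on the plus strand and from 565660 to 568457 on the minus strand. Processed pseudogene copies of BNIP3 and LDHA in the table held 0.385% and 0.149% of their parent gene's reads.

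Of 23 gene lists, 13 passed camera, 8 up and 5 down, but 2 with an estimated correlation, glycolysis and HIF targets. None of the other 21 lists passed with an estimated correlation in any of 21 alternatives. That form was stricter also where correlation was low. The autophagy list had an estimated correlation of -0.04, yet its unadjusted camera p went from 0.000294 to 0.0173. A lost pass is therefore not by itself a sign of correlation between the genes of a list. The estimated correlation was also low for coagulation (0.02) and heat shock proteins (0.07). In the other lists that lost the pass it was well above the preset 0.01, from 0.27 (ribosome biogenesis) to 0.70 (mitochondrially encoded proteins). In fry's directional test, which is against no change and not against other genes, 3 lists passed. Without hypoxia replicate 2, camera passed 4 lists: glycolysis and glucose uptake, HIF targets, the nuclear-encoded respiratory chain and the mitochondrially encoded proteins.

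The genes of glycolysis and glucose uptake moved up together. All 24 tested members had a positive log2 fold change, with a median of 1.07, a 2.10-fold rise. Of these, PFKFB4, SLC2A1, ENO2, PGK1 and LDHA rose and 19 did not pass the test over all genes, while 18 rose with p adjusted over the list alone. Camera placed the list above other genes (adjusted p = 1.41e-46), and it did so with an estimated correlation too (adjusted p = 0.0296), there in 12 of 21 alternatives. Fry's directional test against no change gave an adjusted p of 0.00553. GAPDH, a glycolytic enzyme often used as a reference gene, stood at 110127 ± 18641 in normoxia and 166702 ± 17942 in hypoxia, with a log2 difference of 0.61 (95% interval 0.12 to 1.09, adjusted p = 1.00 by limma).

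HIF target genes outside glycolysis formed the list with the highest median. All 22 tested members were positive, with a median log2 fold change of 1.62, a 3.08-fold rise. ANGPTL4 and BNIP3 rose and 20 did not pass over all genes, while 19 rose with p adjusted over the list alone. The list passed camera (adjusted p = 5.62e-51), also with an estimated correlation (adjusted p = 0.00773), there in 16 of 21 alternatives. Fry gave an adjusted p of 0.00254. VEGFA, the angiogenic growth factor, stood at 165 ± 46.2 in normoxia and 477 ± 138 in hypoxia. Its log2 difference of 1.39 (95% interval 0.57 to 2.21) did not pass the limma test (adjusted p = 0.863), whereas DESeq2 gave an adjusted p of 0.0146 and the other alternatives ranged from 0.000301 to 1.00. Ranges over alternatives, here and below, include the fit with library quality weights, whose estimation did not converge. CA9, the membrane carbonic anhydrase, was below the filter on low values. It had 2, 0 and 0 reads in the normoxia libraries and 10, 38 and 24 in the hypoxia libraries, with an adjusted p of 0.0273 by DESeq2 and 0.438 by edgeR, and its exons share 643 bp with ARHGEF39 on the opposite strand.

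Members of the oxygen-sensing system itself went in different directions, and none of its 9 tested members passed over all genes. With p adjusted over the list alone, 1 rose and 1 fell. HIF1A, which encodes the oxygen-regulated HIF-1 alpha subunit, stood at 2713 ± 1432 in normoxia and 778 ± 264 in hypoxia, a log2 difference of -1.67 (95% interval -2.73 to -0.60, adjusted p = 0.998). Its groups did not overlap, and DESeq2 gave an adjusted p of 0.0206, with a range of 0.000775 to 1.00 over all alternatives. EGLN1, the main prolyl hydroxylase that marks HIF alpha subunits for destruction, stood at 419 ± 52.1 and 911 ± 245, a log2 difference of 1.07 (95% interval 0.45 to 1.69, adjusted p = 0.821). EPAS1, which encodes HIF-2 alpha, stood at 4663 ± 1624 and 4872 ± 2052, a log2 difference of 0.02 (95% interval -0.95 to 0.99) whose sign turned in 6 of 24 alternatives. ARNT, the shared beta subunit, stood at 326 ± 34.4 and 355 ± 71.7, a log2 difference of 0.11 (95% interval -0.51 to 0.72) that was negative in 2 of 23 alternatives. The list as a whole did not pass camera (adjusted p = 0.977), and its mean of -0.08 and median of 0.04 differed in sign.

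**Figure D2:**
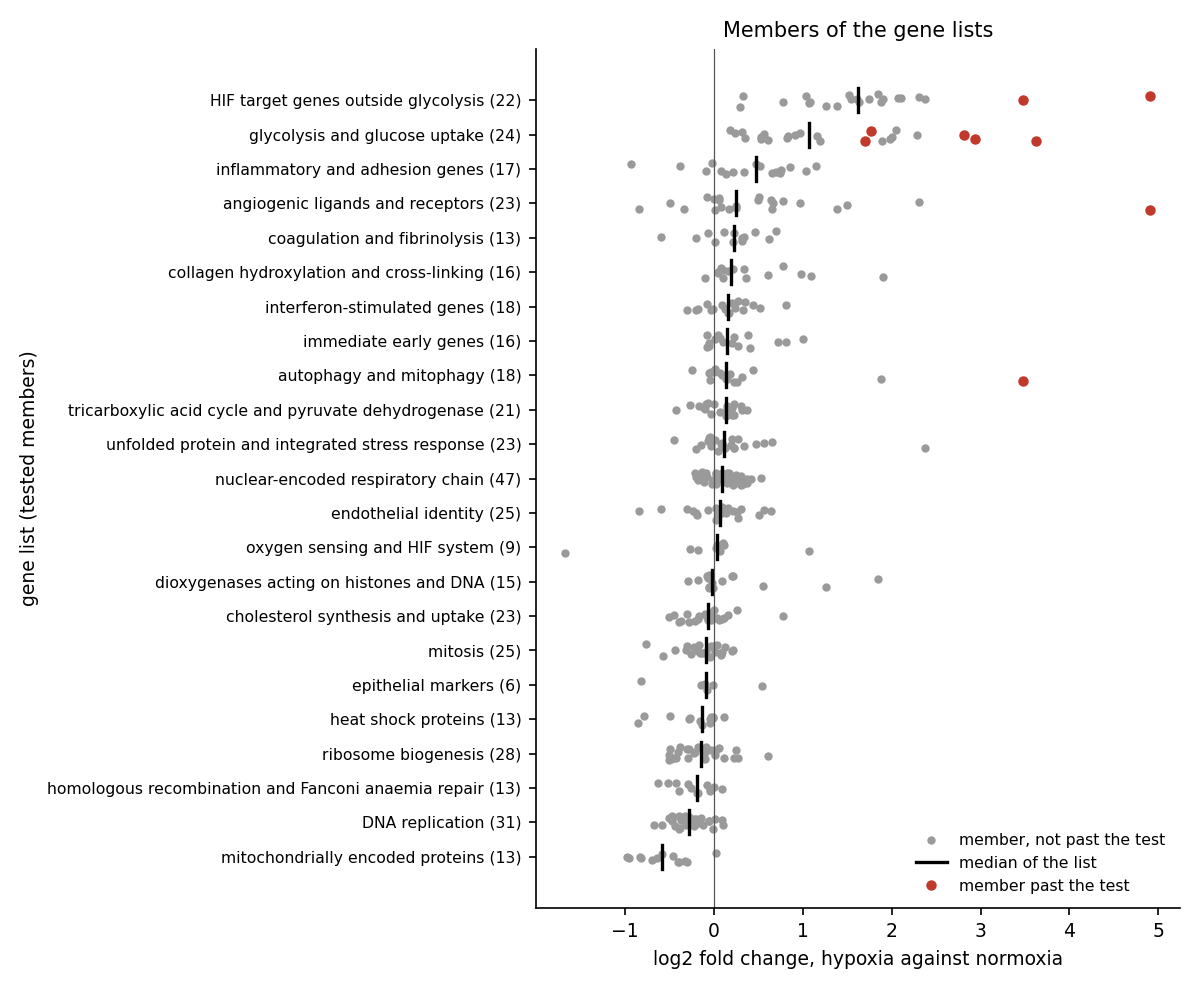
Log2 fold changes, hypoxia against normoxia, of the tested members of the 23 lists with at least 5 tested members, 1 point per gene (red past the test, grey not past it), with a black line at each list's median and the number of tested members in brackets. The lists of HIF targets (median 1.62) and glycolysis (median 1.07) lie to the right of 0 in every member, and the mitochondrially encoded proteins (median -0.59) lie lowest.

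Autophagy and angiogenic lists each held 1 member past the test over all genes. Among 18 tested genes of autophagy and mitophagy, BNIP3 rose and 17 did not pass, with 2 rising over the list alone. Its relative BNIP3L stood at 651 ± 267 and 2312 ± 418, a log2 difference of 1.88 (adjusted p = 0.165, 0.000485 by DESeq2, 3.89e-06 to 1.00 over alternatives). The autophagy list had a median log2 fold change of 0.14. It passed camera (adjusted p = 0.000967) and fry (adjusted p = 0.00369), but had an adjusted p of 0.133 with an estimated correlation and 0.0635 by camera without hypoxia replicate 2. Among 23 angiogenic ligands and receptors, ANGPTL4 rose and 22 did not pass, with 3 rising over the list alone. Adrenomedullin, encoded by ADM, stood at 716 ± 180 and 3721 ± 1578, a log2 difference of 2.31 (adjusted p = 0.107, 1.20e-06 by DESeq2, 1.20e-06 to 0.728 over alternatives). The angiogenic list had a median log2 fold change of 0.25. Its adjusted p was 3.17e-06 by camera, 0.490 with an estimated correlation and 0.290 by camera without hypoxia replicate 2. BNIP3 and ANGPTL4 are also members of the HIF target list, so these lists are not separate evidence from it.

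Among 16 genes of collagen hydroxylation and cross-linking, none passed over all genes and 1 rose over the list alone. The prolyl 4-hydroxylase subunits P4HA1 and P4HA2 had log2 differences of 1.91 (adjusted p = 0.212, 0.00241 by DESeq2, 2.71e-06 to 1.00 over alternatives) and 1.09 (adjusted p = 1.00, 0.0135 with the GC-trend covariate, 0.00162 to 1.00 over alternatives). Both ranges include the fit with library quality weights that did not converge. DESeq2 did not call P4HA2 (adjusted p = 0.860). The collagen list had a median log2 fold change of 0.19. It passed camera (adjusted p = 0.000143), with an adjusted p of 0.490 with an estimated correlation and by camera 0.111 without normoxia replicate 3 and 0.290 without hypoxia replicate 2. Of 15 dioxygenases acting on histones and DNA, none passed over all genes and 1 rose over the list alone. The histone demethylases KDM3A, at 470 ± 109 and 1747 ± 344, and KDM4B, at 1018 ± 298 and 2657 ± 1497, had log2 differences of 1.85 (adjusted p = 0.107) and 1.26 (adjusted p = 1.00). DESeq2 gave an adjusted p of 5.68e-06 for KDM3A (3.28e-06 to 0.816 over alternatives), and limma after the GC and length correction gave 0.0218 for KDM4B (0.00103 to 1.00 over alternatives). DESeq2 did not call KDM4B (adjusted p = 0.271). The median of this list was -0.02 and its mean 0.23, and it did not pass camera (adjusted p = 0.112, 0.561 with an estimated correlation). With the preset correlation it did pass, upward, in 7 of 21 alternatives, with an adjusted p of 0.0124 after the GC and length correction (0.480 with an estimated correlation), 0.0242 without normoxia replicate 1, 0.00480 without hypoxia replicate 1 and 0.0286 without hypoxia replicate 3.

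Cell identity genes held no member past the test. Of 25 tested endothelial identity genes, 18 were positive, with a median log2 fold change of 0.07 and a camera adjusted p of 0.591, or 0.922 with an estimated correlation. With the preset correlation this list passed downward without normoxia replicate 3 (adjusted p = 0.0434), and upward without normoxia replicate 1 (0.0301), without hypoxia replicate 1 (0.00116) and with the GC-trend covariate (0.000117). The VEGF receptor KDR stood at 524 ± 236 and 297 ± 180 and the surface sialomucin CD34 at 1583 ± 815 and 2456 ± 1167. Among 6 epithelial markers the median was -0.09 (camera adjusted p = 0.314), with MUC1 at 64.6 ± 35.6 and 93.6 ± 37.1. Only 3 fibroblast and mural markers and 1 leukocyte marker reached the filter, too few for a list test. FAP stood at 299 ± 230 and 310 ± 49.9, ACTA2 at 142 ± 26.3 and 165 ± 46.7, and LYZ at 55.1 ± 41.4 and 51.2 ± 32.2, and the sign of the log2 difference turned in 2, 2 and 9 of 23 alternatives.

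Transcripts of mitochondrial energy metabolism held no gene past the test. Of the 13 mitochondrially encoded proteins, 12 had negative log2 fold changes, with a median of -0.59. Camera placed this list below other genes (adjusted p = 2.87e-06), with an adjusted p of 0.490 with an estimated correlation. MT-ND6 stood at 8503 ± 5260 and 4330 ± 2183 and MT-ND5 at 25178 ± 17195 and 12391 ± 5759, with SDs in normoxia above the difference between the group means. MT-ND6 lies on the minus strand from 14149 to 14673, next to MT-ND5 on the plus strand, which ends at 14148. With the strand setting not given, reads of these neighbours may not be fully told apart. The share of reads from mitochondrially encoded mRNA was 4.83%, 3.44% and 3.11% in normoxia and 3.84%, 2.56% and 1.69% in hypoxia. The list's median was -0.25 without hypoxia replicate 3, -0.39 without normoxia replicate 1 and -0.89 without hypoxia replicate 1. Of 47 nuclear-encoded respiratory chain genes, 35 were positive, with a median of 0.10 and a camera adjusted p of 0.0577 (0.703 with an estimated correlation), but 0.0478 without normoxia replicate 3 and 1.49e-07 without hypoxia replicate 2. COX6A1 and NDUFA1 had the largest differences in this list, 0.53 and 0.42 on the log2 scale, and a pseudogene copy of COX6A1 held 13.0% of its reads. The exons of NDUFA1 share 341 bp (44.5% of their length) with RNF113A on the opposite strand. The 21 tricarboxylic acid cycle and pyruvate dehydrogenase genes had a median of 0.13 (camera adjusted p = 0.366), with OGDH at -0.42 and PDHB at 0.37.

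Proliferation and biosynthesis lists leaned down by small amounts, with no member past the test. Of 31 DNA replication genes 28 were negative, with a median of -0.28 and a camera adjusted p of 3.11e-05, but 0.561 with an estimated correlation and by camera 0.216 without normoxia replicate 3 and 0.290 without hypoxia replicate 2. MCM5, part of the replicative helicase, stood at 2885 ± 811 and 1928 ± 561, and CDC25A at 238 ± 28.9 and 164 ± 104. Of 25 mitosis genes 16 were negative (median -0.09, camera adjusted p = 0.189, 0.793 with an estimated correlation), with MKI67 at 930 ± 511 and 494 ± 49.9 and CENPF at 490 ± 540 and 218 ± 19.7. CENPF stood at 148, 208 and 1113 in normoxia replicates 1, 2 and 3 and at 201, 213 and 240 in hypoxia. Its higher normoxia mean rests on normoxia replicate 3. MKI67 stood at 610, 661 and 1519 in normoxia and 491, 545 and 446 in hypoxia. With the preset correlation the mitosis list passed downward without normoxia replicates 1 and 2 and hypoxia replicate 1, left out in turn (adjusted p = 0.00976, 0.00417 and 0.000175). Without normoxia replicate 3 its camera adjusted p was 0.111. It passed camera in 5 of 21 alternatives, and its direction matched the main fit in 19 of 21. The homologous recombination and Fanconi anaemia list passed camera (adjusted p = 0.0314) with a median of -0.19, and had an adjusted p of 0.561 with an estimated correlation and by camera 0.939 without normoxia replicate 3 and 0.707 without hypoxia replicate 2. After the GC and length correction the camera adjusted p of that list was 0.0542. FANCA and RAD54L differed by -0.62 and -0.51. The exons of RAD54L share 806 bp (25.1% of their length) with the more abundant LRRC41 on the opposite strand. Ribosome biogenesis had a median of -0.15 (camera adjusted p = 0.0201, 0.561 with an estimated correlation), with 0.639, 0.510 and 0.0952 by camera without normoxia replicate 3 and hypoxia replicates 2 and 3 in turn. PPAN and POLR1A differed by 0.60 and -0.51, and the exons of PPAN share 1447 bp with the read-through gene PPAN-P2RY11.

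Stress and signalling lists held no member past the test. Of 17 inflammatory and adhesion genes 13 were positive, with a median of 0.48 (camera adjusted p = 0.0206, 0.561 with an estimated correlation), and the chemokines CXCL1 and CXCL3 differed by 1.15 and 1.04. By camera its adjusted p was 0.695, 0.378 and 0.205 without normoxia replicate 2 and hypoxia replicates 1 and 2 in turn. Coagulation and fibrinolysis genes had a median of 0.23 (camera adjusted p = 0.0379, 0.490 with an estimated correlation), with the plasminogen activator PLAT at 1140 ± 162 and 1790 ± 471. That list passed camera in 9 of 21 alternatives, with an adjusted p of 0.113, 0.159 and 0.446 without normoxia replicates 1 and 2 and hypoxia replicate 2 in turn. After the GC and length correction its camera adjusted p was 0.0678. Immediate early genes had a median of 0.15 (camera adjusted p = 0.0333, 0.561 with an estimated correlation), with DUSP1 (adjusted p = 1.00, 0.937 by DESeq2, 0.0208 with the GC-trend covariate, 0.00371 to 1.00 over alternatives) and NR4A2 at 1.00 and 0.82. By camera their adjusted p was 0.377, 0.491 and 0.986 without normoxia replicates 2 and 3 and hypoxia replicate 2 in turn. It was 0.0678 after the GC and length correction. Heat shock proteins had a median of -0.13 (camera adjusted p = 0.0298, 0.490 with an estimated correlation), with 0.533 and 0.256 by camera without normoxia replicate 3 and hypoxia replicate 2 in turn. The near-identical paralogues HSPA1A and HSPA1B, whose reads can be split between them, differed by -0.78 and -0.86.

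For 3 remaining lists camera gave an adjusted p above the threshold with all libraries and the main filter and scaling. The unfolded protein and integrated stress response had a median of 0.11 (adjusted p = 0.0538, 0.561 with an estimated correlation), and passed with the preset correlation in 9 of 21 alternatives, with 0.000790 without normoxia replicate 3 and 0.000237 without hypoxia replicate 3. Within it DDIT4, an inhibitor of mTORC1 signalling, stood at 861 ± 669 and 3353 ± 1383, a log2 difference of 2.38 (SE 0.76, adjusted p = 1.00), and DDIT3 differed by 0.66. Cholesterol synthesis and uptake had a median of -0.07 (adjusted p = 0.111, 0.561 with an estimated correlation, 0.0319 without normoxia replicate 3 and 0.0116 without hypoxia replicate 3), with CYP51A1 at 0.78 and TM7SF2 at -0.50. The exons of CYP51A1 share 2844 bp (79.35% of their length) with AC000120.2 on the same strand. Interferon-stimulated genes had a median of 0.16 (adjusted p = 0.143, 0.561 with an estimated correlation, 0.00546 without normoxia replicate 2), with IFITM1 at 0.81 and IFI6 at 0.51, the latter negative in 2 of 24 alternatives. ACTB, the other common reference gene, stood at 82815 ± 20180 and 62898 ± 10810, a log2 difference of -0.38 (95% interval -0.96 to 0.20).

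MIR210HG was the only lncRNA gene past the test, against 9 protein-coding genes. That is 10% of the genes called in these classes, beside 5.21% of the genes tested (507 lncRNA and 9230 protein-coding genes), a difference that Fisher's exact test did not separate from chance (two-sided p = 0.414). DESeq2 also called the lncRNA genes PDK1-AS1, SAP30-DT, LUCAT1, LINC01615 and LINC02970, higher in hypoxia. Limma after the GC and length correction called LINC01615 too (adjusted p = 0.0156). The share was not compared for those calls. MIR210HG is weakly expressed and its normoxia values were 7.41, 28.4 and 7.52.

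The largest axis of variation between the libraries lay within the groups. The first principal component of the log2 values carried 57.8% of the variance and placed normoxia replicate 3 at the far end, with normoxia replicate 1 and hypoxia replicate 2 together at the other. Across genes, the deviation of a library from the gene mean rose with GC content in normoxia replicates 1 and 2 and hypoxia replicate 2 (Spearman rho 0.688, 0.263 and 0.495) and fell with it in normoxia replicate 3 and hypoxia replicates 1 and 3 (rho -0.562, -0.341 and -0.379). Genes are not independent replicates in these correlations. Normoxia replicate 3 also had the fewest genes detected, 16741 beside 18214 to 18858 in the other libraries. Its shares of reads from mitochondrial rRNA (1.83%, beside 0.707% to 1.42%) and from genes neither protein-coding nor lncRNA (3.31%, beside 1.71% to 2.84%) were the highest of the 6 libraries.

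**Figure D3:**
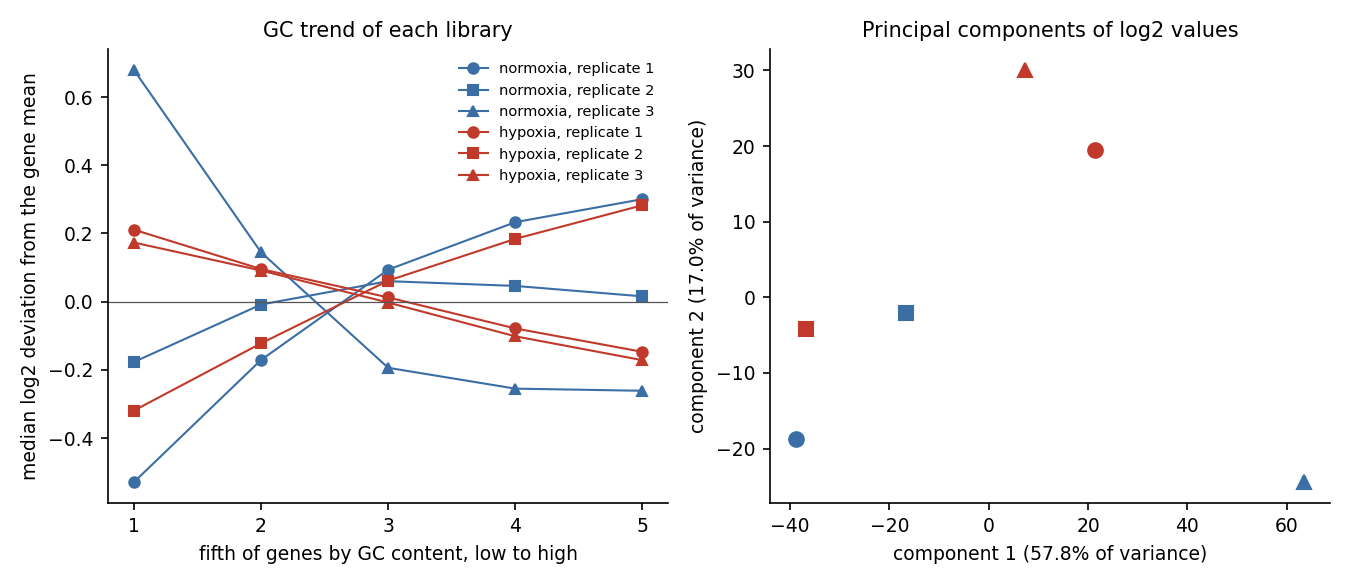
Left, the median log2 deviation of each library from the gene mean in 5 equal bins of the genes tested by GC content (x axis, low to high); right, the 6 libraries on the first and second principal components, which carry 57.8% and 17.0% of the variance, with groups by colour and replicates by marker shape. In the bin of lowest GC content the medians run from -0.53 in normoxia replicate 1 to 0.68 in normoxia replicate 3, and the first component does not part the groups.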

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

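The corrections for GC content and gene length, the GC-trend covariate, library quality weights, edgeR, DESeq2 and the fit on deposited values were chosen after seeing the data. Against 10 genes past the test, all by at least 2-fold, limma called 4 with no filter on low values, where 22153 genes were tested, 22 with the GC correction, 28 with GC content and gene length, and 64 with the GC-trend covariate, 62 of them by at least 2-fold. DESeq2 called 58, and 10 of these lay outside the genes tested by limma. Library quality weights gave 4667 genes, 312 by at least 2-fold, but their estimation stopped before converging, so this count is not a usable estimate. Leaving out 1 library gave 1 (without hypoxia replicate 3) to 24 genes (without normoxia replicate 3), at any size and at 2-fold or more. The cause of these differences, the lower number of samples included, was not tested. The other settings without a replicate block gave 7 to 12 genes, edgeR 9.

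Of 23 gene lists, 13 passed camera, 4 without hypoxia replicate 2 and 15 without normoxia replicate 1, 2 with an estimated correlation and 3 in fry's directional test. The other alternatives gave 11 to 15. Over the 58 named genes and their alternatives, 1246 values stayed on the same side of the threshold, 65 passed it where the gene had not, 45 no longer passed it, and no called gene turned direction. These values include the fit with library quality weights.

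Correlations of libraries with the same number, after removing group means, were -0.398, 0.240 and 0.224. The best partners of normoxia replicates 1, 2 and 3 were hypoxia replicates 2, 2 and 1. These values showed no consistent pairing by number but cannot exclude one, and the labels do not state whether samples were paired. A replicate block gave 19 genes, and 23 with the GC and length correction, all by at least 2-fold, and left the count of lists at 13 without that correction. No scaling moved the median log2 fold change of all genes by over 0.1.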

Other observations

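The correlation of the largest axis with GC content, the share of spread left after correction, the depth comparison and the count after GC correction were tests chosen only after the result was seen, and the genes in the next paragraph were chosen after their values were seen.

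Beyond the 10 genes past the test, 15 genes were called by limma after correction for GC content and gene length, by limma with the GC-trend covariate and by DESeq2. They include PPP1R3C and PPP1R3G, which encode subunits that direct protein phosphatase 1 to glycogen. PPP1R3C stood at 29.6 ± 4.54 in normoxia and 277 ± 154 in hypoxia, and PPP1R3G at 19.1 ± 2.81 and 142 ± 26.4. The lactate exporter SLC16A3 stood at 4339 ± 2127 and 15853 ± 4202, the hexokinase HK2 at 188 ± 29.7 and 823 ± 333, and the glycolytic mutase PGAM1 at 5642 ± 520 and 12633 ± 228. FAM162A stood at 413 ± 162 and 1720 ± 125, NDRG1 at 1252 ± 127 and 4436 ± 1812, and ARRDC3 at 266 ± 141 and 1228 ± 309. DEPP1, which shares exon sequence with RASSF4, had a log2 difference of 3.34 and an adjusted p of 0.0518 by limma.

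DESeq2 called 52 genes higher and 6 lower in hypoxia. Among the lower ones, TXNIP, an inhibitor of glucose uptake, stood at a mean of 304 in normoxia and 69.5 in hypoxia, the guanine nucleotide exchange factor RAB3IL1 at 207 and 73.6, and the adhesion protein FLRT2 at 860 and 385. HIF1A was also among them. Among the higher ones, the glucose transporter SLC2A3 stood at 1153 and 5732, and IGFBP3 at 104 and 309.

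PPP1R3C and PPP1R3G led to the hypothesis that hypoxia raises glycogen metabolism genes as a group. It was tested on 12 other genes of glycogen metabolism that reached the filter and had not been looked at. Their median log2 fold change was 0.07, and 7 of them were positive. The camera test of limma gave an adjusted p = 0.958, with this list the only 1 adjusted over, so the hypothesis found no support in these members.

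The largest axis of variation runs within the groups, with normoxia replicate 3 at one end. A lower read total of that library is excluded, since it held 1.04 times the median reads of the others, but its quality is not, since it had the fewest genes detected (16741) and the highest mitochondrial rRNA share (1.83%). The correction for GC content and gene length left 64.8% of the within-group sum of squares, which also holds variation outside this axis. After it the first component still carried 46.8% of the variance, with normoxia replicate 3 at one end. An incomplete correction could leave this too, so GC content with gene length as the whole cause is not excluded. GC bias between libraries may contribute, since the gene loadings correlated with GC content (Spearman rho -0.642). The mitosis and DNA replication genes lay toward normoxia replicate 3, at percentile 100 of 10000 lists matched on GC content and level, but so did epithelial markers (99.7) and inflammatory genes (99.9), with endothelial identity (0), collagen (0), angiogenic (0.01) and HIF target genes (0.01) at the other end. The axis is therefore not particular to growth, the percentiles are descriptive because genes of a list vary together, and which state of the cells or libraries lies behind it stays open.

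The number of genes past the test was 10 as planned and 22 after the GC correction, which could mean that GC-related spread between libraries hides changes. Of the 10 splits of the 6 libraries into 3 and 3, 2 gave at least 10 genes, and the highest other, normoxia replicates 1 and 2 with hypoxia replicate 2 against the rest, gave 1494, which points to a structure of the samples along the GC trend. After the correction for GC content and gene length the real split gave 28 genes, the highest other 1, and 1 of the 10 splits, the real one, gave as many. With 10 splits no share under 0.05 can be reached.

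The mitochondrially encoded transcripts had a median log2 fold change of -0.59. The trend with GC content and gene length over all genes tested did not account for it, since the median was -0.71 after the correction. A bias particular to these transcripts was not tested. Hypoxia replicate 3 alone may carry much of the difference, since the median was -0.25 without it, and it was -0.39 without normoxia replicate 1 and -0.89 without hypoxia replicate 1. A lower mitochondrial RNA content in hypoxia stays open as a hypothesis, and mitochondrial DNA copy number and transcript levels in more cultures would test it.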
